A study of Escherichia coli K-12 with 12 samples.

How the data were processed

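Values were the log2 expression values deposited by the authors, 7312 probe sets on 12 arrays. Per the submitters' processing notes they came from GCRMA, a background correction and summary method that uses probe sequence; its version is not given in the sources used here. That the unit was log2 was inferred from the range of the values, about 1 to 15. They were used without further scaling. No value was missing and 0 columns were left unused. Raw probe intensities were not analysed here.

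Probe sets were paired with genes by Entrez gene identifier, with locus tags and symbols from assembly ASM584v2 of MG1655. As listed, 3804 probe sets had 1 symbol, 594 had several and 2914 had none. After pairing, 4286 belonged to 1 MG1655 gene, 42 to several and 2984 to none. Only probe sets of 1 gene were tested. Where a gene had several, as 78 genes did, the probe set with the highest mean over the 12 arrays was kept and 101 others were left out. This gave 4185 genes, 58 of them read through an intergenic probe set and 80 through a probe set that can cross-hybridise. The 22 Affymetrix controls were left out, and 59 probe sets for phage, plasmid and vector sequences served to define background. A gene was at background on an array if its value was at or below the highest of these, which ran from 2.12 to 2.77 over the arrays. Of the 59, 0 were called in any comparison.

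A linear model with 1 mean per group was fitted over the 12 arrays in limma, with moderated variances (8 residual and 3.56 prior degrees of freedom). From it came the mutant minus wild type difference in each phase, the stationary minus exponential difference in each genotype, and the interaction. P values were adjusted by Benjamini and Hochberg over the 4185 genes of each comparison, and genes with an adjusted p under 0.05 were called. The calls at least 2-fold are a subset of these. "Adjusted over the list alone" means that the adjustment used only the members of that list. The number of arrays limits precision.

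Gene lists were 26 in number and taken from textbook knowledge. Each was tested with camera, a competitive test in limma, with a preset correlation between genes of 0.01, and adjusted over the 26 lists of a comparison. As an alternative the correlation was estimated for each list. The comparisons, the lists, the calls and the other settings below were chosen before the data were examined. Leaving out the flagellar genes was added after seeing the data.

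Genes were named by rule. The deleted gene came first. In the mutant against wild type comparisons and in the wild type phase comparison, the rule took the 10 highest and 10 lowest log2 fold changes among called genes whose groups did not overlap. In the mutant phase comparison it took 5 and 5, and in the interaction 5 and 5 without the overlap condition. From each list it took up to 4 called members with the largest changes, or, where none was called, up to 2 with the smallest adjusted p. Not every gene so chosen is printed; the tables hold the rest.

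Settings tried besides were the replicate number as a block, quantile normalization once more, median centring, leaving out the dimmest 25% of genes, and testing all probe sets except controls. Others were a variance trend with robust moderation, array weights, a threshold of 0.01, the 6 arrays of the groups compared alone, and each replicate left out in turn.

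The code was tested on simulated data before use, with 200 of 4185 genes changed in each of 5 simulations. It called 14% of genes changed by 0.5 on the log2 scale, 80% at 1, 98.8% at 2 and 100% at 4, with 7 false calls per simulation and 0 in comparisons without change. A list shifted by 0.5 was called in 5 of 5 simulations and 0 other lists were. Genes were simulated independently of each other, so this does not show how often lists whose genes vary together are called falsely.

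The work used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.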

Results

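The series measured messenger RNA in Escherichia coli K-12 MG1655 and in a derivative from which rpoS had been precisely removed by Red recombination. RpoS is the sigma factor that directs RNA polymerase to promoters of the general stress response. Both strains were grown with shaking at 37 °C in M63 minimal medium holding 0.2% glucose. Cultures started from separate single colonies and were harvested at an OD600 of 0.3, during exponential growth, or of 1.5, in stationary phase. The 4 groups of genotype and phase held 3 arrays each, 12 in all. RNA was hybridised to the Affymetrix E. coli Antisense Genome Array, which reads each gene through a probe set of short oligonucleotides, and 4185 genes were tested. The number of arrays limits the precision of every value. Median SDs across genes were 0.244 in each exponential group, 0.160 in the stationary wild type and 0.151 in the stationary mutant, all on the log2 scale. Arrays of 1 group correlated across genes with r between 0.953 and 0.991. The first principal component, with 48.8% of the variance, parted the growth phases, and the second, with 26.9%, parted the genotypes.

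The deleted gene was examined first on every array. In exponential phase rpoS (b2741) read 11.92, 11.34 and 11.51 on the log2 scale in wild type replicates 1 to 3, and 2.56, 3.09 and 2.65 in the mutant replicates. In stationary phase it read 11.58, 11.49 and 11.40 in the wild type and 2.13, 1.65 and 1.90 in the mutant. In the stationary mutant all 3 values lay at or below the highest of 59 probe sets for foreign sequences on the same array, the level called background here. Where a group was at background on all of its arrays, the fold is given as a lower bound, from the brighter group's mean against the mean of that highest foreign value or the gene's own value, whichever was higher on each array. By that rule rpoS was at least 608-fold lower in the stationary mutant (adjusted p = 3.41e-11).

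The comparison of the mutant with the wild type in exponential phase asked which genes depended on RpoS while cells were still growing. In the mutant 14 of 15 acid resistance genes and 28 of 93 general stress genes were lower, while 53 of 54 flagellar genes and 14 of 17 genes of the tricarboxylic acid cycle were higher. The last of these list shifts was lost with an estimated correlation (adjusted p = 0.136). The gene gadB (b1493), for a glutamate decarboxylase that consumes protons, dropped by 8.46 on the log2 scale (SE 0.31, adjusted p = 2.03e-09), from 11.96 ± 0.63 to 3.50 ± 0.51 (SD, n = 3). Expression of hdeA, a periplasmic acid chaperone, went from 12.98 ± 0.25 to 8.18 ± 0.08 (SD, n = 3). Across the genome 175 genes were higher and 148 lower in the mutant, of which 120 and 103 changed at least 2-fold. After quantile normalization the split was 155 higher to 173 lower, and the share of higher genes went from 54.2% to 47.3%. Without exponential wild type replicate 1 the number of higher genes was 285. Without the 54 flagellar genes, an alternative chosen after seeing the data, it was 116.

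Of the 15 genes measured for glutamate-dependent acid resistance, 14 fell, 0 rose and 1 did not pass. Adjusted over the list alone, 14 were lower. The list median was −2.566 on the log2 scale (adjusted p = 1.97e-26 by camera, and adjusted p = 0.0134 with an estimated correlation). The second decarboxylase gene gadA fell by 3.27 (SE 0.47) and gadC, for the glutamate antiporter, fell by 4.0 (SE 0.16). The acid chaperone gene hdeB fell by 4.16 (SE 0.14), and hdeD, for a membrane protein of acid resistance, fell by 4.07 (SE 0.24). Among 93 RpoS-dependent general stress genes, a list fixed from textbook knowledge, 28 fell, 1 rose and 64 did not pass. Adjusted over the list alone, 38 were lower and 1 higher. Their median was −0.407 (adjusted p = 4.6e-16, and adjusted p = 0.0151 with an estimated correlation). The hydrogenase 1 genes hyaA fell by 4.43, and its partner hyaB fell by 2.57. The quinone oxidoreductase gene wrbA fell by 2.66, and sra, for a ribosome-associated protein, fell by 2.13. The gene that rose was msrB, a methionine sulfoxide reductase, at 1.78 (adjusted p = 0.00321), picked out after its value was seen.

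Flagella and chemotaxis genes were higher in the exponential mutant in 53 of 54 cases, and 0 were lower. Adjusted over the list alone, 53 were higher. Their median was 3.797 (adjusted p = 4.56e-110, and adjusted p = 0.000697 with an estimated correlation). The 8 neighbouring genes flhD, flhC, motA, motB, cheA, cheW, tar and tap (b1892 to b1885) were all among those higher. In 6 of these, all except tar and tap, the wild type was at background on all 6 of its arrays, in both phases; tap was at background on 5 and tar on 0. In the mutant cheA, the chemotaxis kinase gene, was at least 809-fold higher (adjusted p = 7.5e-13) and cheW, for its coupling protein, at least 644-fold. The stator genes motB and motA were at least 619-fold and 475-fold higher. The genes of the flagellar master regulator, flhD and flhC, were at least 266-fold and 131-fold higher. Of the chemoreceptor genes, tap was higher too (adjusted p = 1.68e-09), and tar rose by 8.24 (SE 0.35). Outside this segment fliM, for a switch protein, rose by 7.17, flgF, for a rod protein, by 6.20, and fliA, the flagellar sigma factor gene, by 5.21.

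**Figure D1:**
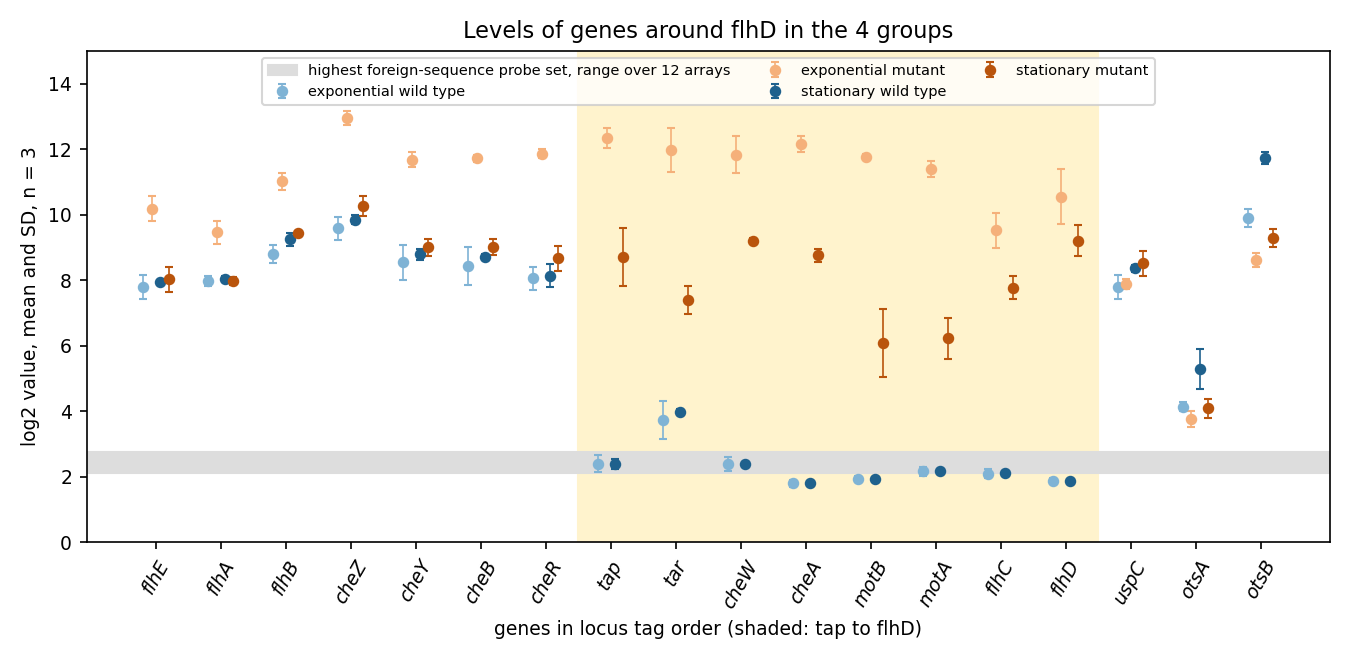
Log2 expression of 18 neighbouring genes from flhE to otsB in locus tag order (x axis), as mean ± SD of 3 arrays (y axis, log2 GCRMA value) for the 4 groups. The grey band spans the highest foreign-sequence probe set over the 12 arrays, from 2.12 to 2.77. Within the shaded segment from tap to flhD the wild type was at background on all 6 of its arrays for 6 genes, on 5 for tap and on 0 for tar, while the mutant means lay above the band.

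Genes of central metabolism also differed in exponential phase. Of 17 tricarboxylic acid cycle genes 14 rose and 0 fell, with 14 higher and 1 lower adjusted over the list alone. The list median was 1.884 (adjusted p = 3.71e-12, but adjusted p = 0.136 with an estimated correlation). The succinate dehydrogenase genes led, with sdhC up by 4.01 (SE 0.62), sdhB by 3.34 (SE 0.45), sdhD by 3.21 (SE 0.48) and sdhA by 2.91 (SE 0.39). Of 24 genes of fermentation and anaerobic respiration 10 fell and 0 rose, with 15 lower and 1 higher adjusted over the list alone (median −0.785, adjusted p = 3.56e-09, but adjusted p = 0.155 with an estimated correlation). Pyruvate formate-lyase, pflB, fell by 2.05, the C4-dicarboxylate transporter gene dcuB by 1.94 and hycE, for a hydrogenase 3 subunit, by 1.76. Of 61 amino acid biosynthesis genes 11 fell and 1 rose, with 21 lower and 2 higher adjusted over the list alone (median −0.595, adjusted p = 1.45e-07, but adjusted p = 0.371 with an estimated correlation). The aspartokinase gene lysC fell by 4.05 (SE 0.40), the diaminopimelate decarboxylase gene lysA fell by 2.57 and dapB, for an earlier enzyme of lysine synthesis, fell by 2.43. The arginine gene argC fell by 1.66, and its call was lost without exponential wild type replicate 1 or 3, without exponential mutant replicate 1 or 3 and with all probe sets (adjusted p = 0.108, 0.168, 0.0817, 0.113 and 0.0723). Glycogen and maltose genes fell in 5 of 15 cases, with 0 higher, and 6 were lower and 1 higher adjusted over the list alone (median −0.406, adjusted p = 0.000401, but adjusted p = 0.283 with an estimated correlation). Among these were the genes for glycogen synthase, glgA, and for debranching enzyme, glgX, which each fell by 2.39. Outside the lists, yjiG fell by 3.34.

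Smaller shifts upward were seen in 4 further lists, and none of these calls held with an estimated correlation. Type 1 fimbriae had 4 of 9 genes higher, 8 adjusted over the list alone (median 0.760, adjusted p = 3.81e-05, adjusted p = 0.211 with an estimated correlation). ATP synthase and NADH dehydrogenase I had 1 of 22 higher, the gene nuoF, and 5 adjusted over the list alone (median 0.535, adjusted p = 9.11e-05, adjusted p = 0.651 with an estimated correlation). Intact cryptic prophages had 3 of 24 genes higher under both adjustments, by all genes and adjusted over the list alone, among them the repressor gene racR at 0.92 (median 0.193, adjusted p = 0.00551, adjusted p = 0.651 with an estimated correlation). That call was also lost when dim genes were left out (adjusted p = 0.170). Ribosomal proteins had 2 of 54 genes higher, rpmE and rpsO, and 2 adjusted over the list alone (median 0.144, adjusted p = 0.0187, adjusted p = 0.785 with an estimated correlation). The ribosomal call was lost after quantile normalization (adjusted p = 0.0691), and without exponential wild type replicate 3 the adjusted p was 0.0561 for rpmE and 0.0543 for rpsO. Without exponential mutant replicate 2 these were 0.0613 and 0.0516. In all 4 fimbrial genes that rose, fimB, fimC, fimD and fimI, the call was lost without exponential wild type replicate 2 (adjusted p = 0.13, 0.0825, 0.0759 and 0.0726) and without exponential mutant replicate 2 (adjusted p = 0.0802, 0.0974, 0.109 and 0.124).

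The remaining lists did not shift as sets in exponential phase, though some members did. Iron acquisition had 5 of 33 genes higher (5 adjusted over the list alone, list adjusted p = 0.0882, but 0.0258 with all probe sets), including exbB, of the complex that energises outer membrane transport, at 1.91 and the iron reductase gene fhuF at 1.58. Glyoxylate bypass and acetate use had 3 higher and 2 lower of 12 (4 and 2 adjusted over the list alone, list adjusted p = 0.397). Isocitrate lyase, aceA, rose by 2.03, and the phosphotransacetylase gene pta fell by 1.62. Oxidative stress defence had 2 higher and 1 lower of 16 (2 and 2 adjusted over the list alone, list adjusted p = 0.939), with the manganese superoxide dismutase gene sodA up by 1.77. Nucleoid proteins and ribosome hibernation had 4 of 16 lower (5 adjusted over the list alone); the list median was 0.133, its mean −0.217 and its test pointed down (adjusted p = 0.454). Glycolysis had 1 higher and 2 lower of 18 (adjusted p = 0.273) and the pentose phosphate pathway 2 lower of 10 (adjusted p = 0.249), with the same counts adjusted over the list alone. Trehalose and osmotic stress had 2 higher and 2 lower of 20, with 3 and 2 adjusted over the list alone (adjusted p = 0.582). Among 13 chromosomal neighbours of rpoS only nlpD, the gene just upstream, changed; it fell by 0.86 (adjusted p = 0.00359; list adjusted p = 0.273, 1 lower adjusted over the list alone).

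The same comparison in stationary phase asked which genes depended on RpoS once growth had slowed. In the mutant 49 of 93 general stress genes and 10 of 15 acid resistance genes were lower, as were 41 of 54 ribosomal protein, 10 of 18 glycolytic and 11 of 18 heat shock genes. The last 3 list shifts were lost with an estimated correlation (adjusted p = 0.0932, 0.126 and 0.0932). The gene dps, for a protein that binds and protects DNA, read 13.45 ± 0.42 in the wild type and 9.0 ± 0.09 in the mutant (SD, n = 3), and thus fell by 4.45 (SE 0.31, adjusted p = 2.57e-06). The gene hchA, for the chaperone Hsp31, fell by 4.03 (SE 0.18, adjusted p = 2.55e-08). In total 256 genes were lower, 196 of them at least 2-fold, and 40 were higher, 19 of them at least 2-fold. After quantile normalization the split was 279 lower to 156 higher, so the share of higher genes went from 13.5% to 35.9%. The number of higher genes was 21 without stationary wild type replicate 3 and 23 without stationary mutant replicate 2. Fitted on the stationary arrays alone, 367 genes were lower and 140 higher, while the exponential arrays alone gave 74 lower and 107 higher. The counts of the main fit, with its pooled variance, therefore do not show which phase had more changed genes.

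Of the 93 general stress genes, 49 fell in the stationary mutant, 0 rose and 44 did not pass, and 60 were lower and 1 higher adjusted over the list alone. The median was −0.846 (adjusted p = 1.5e-36, and adjusted p = 0.00269 with an estimated correlation). Besides dps and hchA, wrbA fell by 3.76 and the protein kinase gene yeaG by 3.65. Of the 15 acid resistance genes 10 fell, 0 rose and 5 did not pass, and 11 were lower adjusted over the list alone (median −1.610, adjusted p = 8.33e-20, and adjusted p = 0.034 with an estimated correlation). Here gadB fell by 9.12 (SE 0.31), gadA fell by 5.79 (SE 0.47), gadC fell by 5.36 (SE 0.16) and hdeA fell by 4.96 (SE 0.15). Trehalose and osmotic stress genes fell in 6 of 20 cases, also 6 adjusted over the list alone, and 0 rose (median −0.169, adjusted p = 0.00432, but adjusted p = 0.108 with an estimated correlation). The periplasmic protein gene osmY fell by 2.59 and the trehalose-6-phosphate phosphatase gene otsB by 2.43, and both are also on the general stress list.

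**Figure D2:**
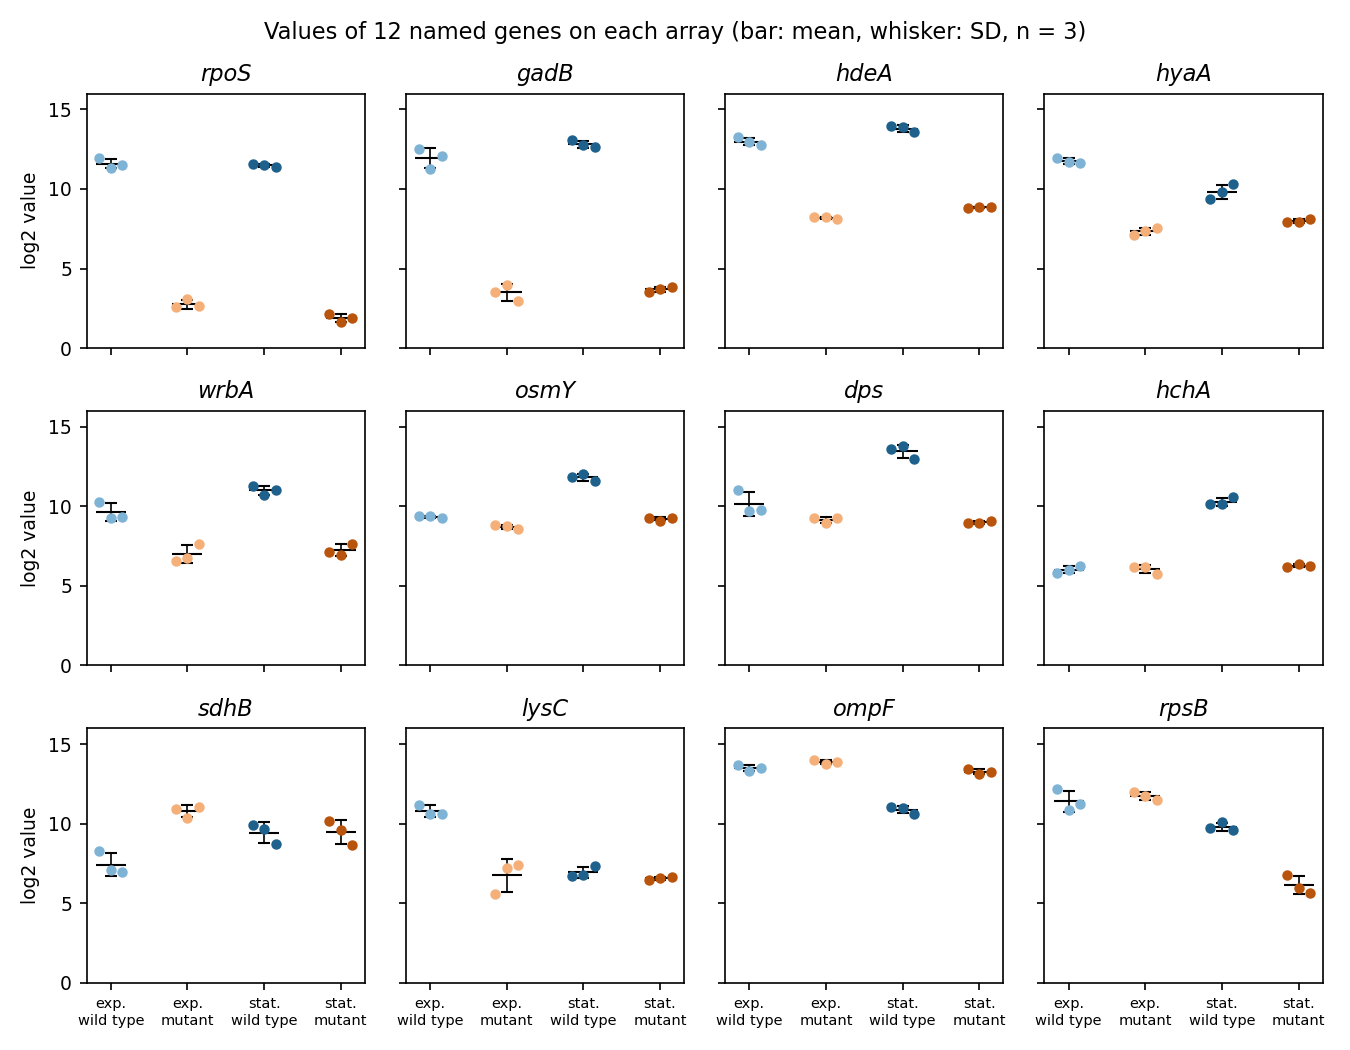
Log2 expression (y axis, log2 GCRMA value) of 12 genes on each of the 12 arrays, by group (x axis), each point 1 array. The genes are rpoS, gadB, hdeA, hyaA, wrbA, osmY, dps, hchA, sdhB, lysC, ompF and rpsB. In stationary phase dps read 13.45 ± 0.42 in the wild type and 9.0 ± 0.09 in the mutant (SD, n = 3).

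Genes for protein synthesis and sugar breakdown were also lower in the stationary mutant. Of 54 ribosomal protein genes 41 fell and 0 rose, with 47 lower adjusted over the list alone (median −1.407, adjusted p = 1.86e-39, but adjusted p = 0.0932 with an estimated correlation). Of these, rpsB fell by 3.68, from 9.81 ± 0.25 to 6.13 ± 0.57 (SD, n = 3), and rpmC fell by 3.46. Of 18 genes of glycolysis and glucose uptake 10 fell and 0 rose, with 12 lower adjusted over the list alone (median −0.864, adjusted p = 4.89e-13, but adjusted p = 0.126 with an estimated correlation). The phosphocarrier gene ptsH fell by 2.57, the class I aldolase gene fbaB by 2.33, the enolase gene eno by 2.23 and gapA, for glyceraldehyde-3-phosphate dehydrogenase, by 2.03. Of 18 heat shock genes 11 fell and 0 rose, with 11 lower and 1 higher adjusted over the list alone (median −1.083, adjusted p = 1.91e-09, but adjusted p = 0.0932 with an estimated correlation). The chaperone genes dnaK and clpB fell by 2.61 and 2.03, and the protease gene clpP by 2.09. Of 16 genes of nucleoid proteins and ribosome hibernation 6 fell and 0 rose, with 8 lower and 1 higher adjusted over the list alone (median −0.602, adjusted p = 6.72e-06, but adjusted p = 0.133 with an estimated correlation). After dps, the members that fell most were yqjD, by 2.38, and sra, by 2.11. The genes dps, yqjD and sra also belong to the general stress list, so the shift is in part shared with that one. The member ihfA, outside the general stress list, read 10.78 in the stationary wild type and 9.22 in the mutant. The list was not tested without its shared members.

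Several lists passed with only a few changed members, and none of these calls held with an estimated correlation. Among 12 genes of glyoxylate bypass and acetate use 3 fell, with 5 lower and 1 higher adjusted over the list alone (median −0.649, adjusted p = 0.00711, adjusted p = 0.425 with an estimated correlation). Malate synthase, aceB, fell by 1.19, and after quantile normalization the list did not pass (adjusted p = 0.0943). Of 21 sigma factors and regulators of RpoS 6 fell, with 6 lower and 1 higher adjusted over the list alone (median −0.124, adjusted p = 0.0334, adjusted p = 0.354 with an estimated correlation, adjusted p = 0.112 after quantile normalization). The envelope stress sigma factor gene rpoE fell by 1.56 and the RNA chaperone gene hfq by 1.48. The pentose phosphate list had 2 of 10 lower, 2 adjusted over the list alone (median −0.098, adjusted p = 0.0218, adjusted p = 0.397 with an estimated correlation, adjusted p = 0.0546 after quantile normalization). Here talA, for transaldolase A, fell by 2.5 and tktB, for transketolase B, by 1.38. Both also belong to the general stress list. ATP synthase and NADH dehydrogenase I passed with 0 of 22 members called under either adjustment, by all genes or adjusted over the list alone (median −0.249, adjusted p = 0.0218, adjusted p = 0.706 with an estimated correlation). It did not pass after quantile normalization (adjusted p = 0.0525) or without dim genes (adjusted p = 0.0619). Its smallest gene p were those of nuoE at −0.60 (adjusted p = 0.179) and atpH at −0.58 (adjusted p = 0.231).

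Higher genes in the stationary mutant included 9 of the 54 flagellar genes, with 10 adjusted over the list alone and 0 lower (median 0.296, adjusted p = 1.47e-12, but adjusted p = 0.115 with an estimated correlation). These were the 8 genes from flhD to tap, of which 6 were at background on all 6 wild type arrays, and 1 other member. In this phase tap too was at background in the wild type. The flhD and cheW genes were each at least 103-fold higher in the mutant, cheA at least 75.7-fold and tap at least 73.1-fold. For flhC the bound was 38.1-fold, for motA 13.1-fold and for motB 11.9-fold, while tar rose by 3.42 (SE 0.35). Apart from these, the porin gene ompF rose by 2.38 (SE 0.15), from 10.88 ± 0.22 to 13.27 ± 0.14 (SD, n = 3), and nmpC, also for a porin, rose by 2.17 (SE 0.37). Type 1 fimbriae had 1 of 9 genes higher, the major subunit gene fimA at 1.47, with 2 higher adjusted over the list alone (median 0.301, adjusted p = 0.00644, but adjusted p = 0.354 with an estimated correlation). Cryptic prophages had 1 of 24 genes higher, also 1 adjusted over the list alone (median 0.376, adjusted p = 0.00071, but adjusted p = 0.425 with an estimated correlation). That gene, essD, rose by 0.66, and its call was lost without stationary wild type replicate 2 (adjusted p = 0.051) and after quantile normalization (adjusted p = 0.0907).

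Some of the lists that did not pass in stationary phase held a few changed genes. In the tricarboxylic acid cycle, 1 of 17 rose, the fumarase gene fumA at 1.56, and 1 fell, the aconitase gene acnA, by 1.68 (list adjusted p = 0.149, the same counts adjusted over the list alone). After quantile normalization this list passed upward (median 0.566, adjusted p = 0.00992). Within oxidative stress defence 3 of 16 fell, 5 adjusted over the list alone (list adjusted p = 0.0842, but 0.0431 without dim genes and 0.0474 with all probe sets); besides dps these were sufA, of iron-sulfur cluster assembly, by 1.61 and sodA by 1.47. Nitrogen limitation had 3 of 26 lower, 3 lower and 1 higher adjusted over the list alone; its median was 0.075, its mean −0.045 and its test pointed down (adjusted p = 0.589). The 3 were arginine breakdown genes, with log2 fold changes of −1.21 for astC, −1.02 for astD and −0.998 for astA. Tryptophanase and amine catabolism had 3 lower and 1 higher of 17, the same adjusted over the list alone, with a median of 0.068, a mean of −0.161 and a test pointing down (adjusted p = 0.498); gabD, for succinate semialdehyde dehydrogenase, fell by 1.37. Fermentation had 2 of 24 lower, 2 adjusted over the list alone, with a median of 0.003, a mean of −0.139 and a test pointing down (adjusted p = 0.498). Glycogen and maltose had 0 of 15 called, 0 adjusted over the list alone, with a median of 0.058, a mean of −0.099 and a test pointing up (adjusted p = 0.898).

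**Figure D3:**
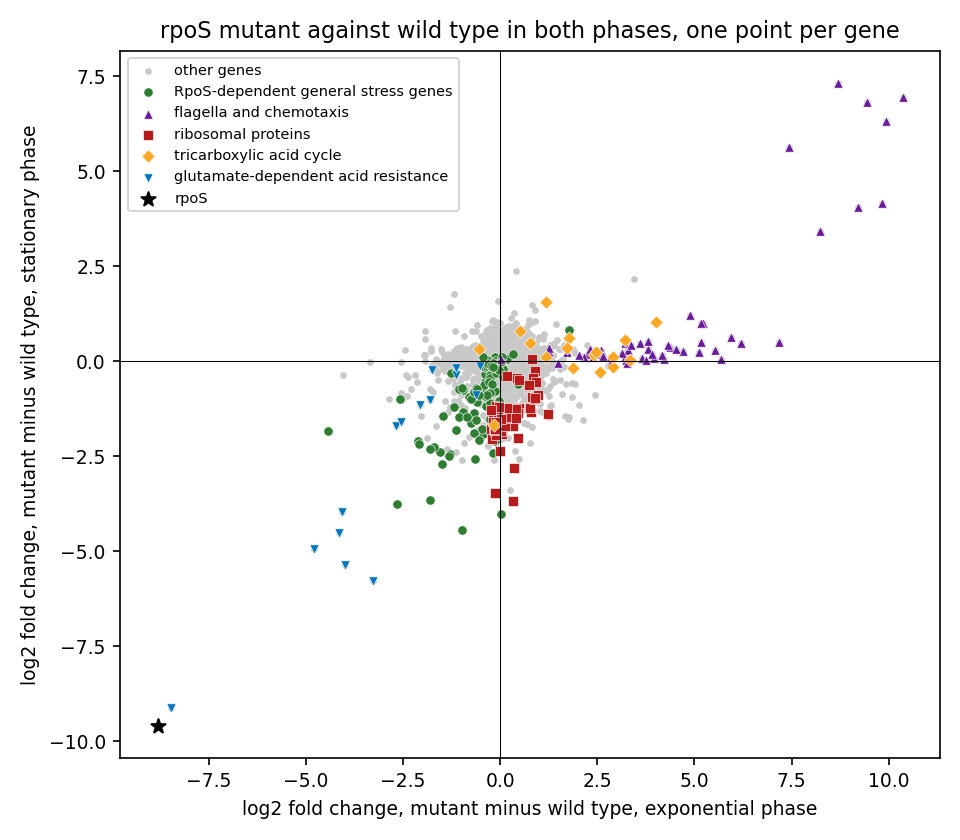
Log2 fold change of the mutant against the wild type in exponential phase (x axis) and in stationary phase (y axis) for 4185 genes, each point 1 gene. Coloured points mark gene lists and the star marks rpoS, at −8.82 in exponential phase and drawn from a mutant value at background in stationary phase, where it was at least 608-fold lower. Across genes r was 0.435.

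The overlap between the phases was counted from arrays that the comparisons did not share. Of the genes lower in the mutant, 60 were lower in both phases, where independent lists would share 9.05. Of those higher, 14 were higher in both phases against 1.67 for independent lists, and 22 were after quantile normalization. The 14 include the 8 neighbouring genes from flhD to tap, which are not independent of each other. In 6 of these 8 the wild type was at background on all 6 of its arrays. Only 6 genes were higher in exponential and lower in stationary phase (10.7 for independent lists), and 0 the other way (1.41). Fold changes of the phases correlated across genes with r = 0.435 and Spearman rho = 0.124; genes are not independent replicates.

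The comparison of stationary with exponential phase in the wild type gave the growth phase response of cells that hold RpoS. In stationary phase 51 of 93 general stress genes were higher and 4 lower, and 7 of 12 genes of glyoxylate bypass and acetate use were higher and 2 lower. Lower were 45 of 61 amino acid biosynthesis genes, 41 of 54 ribosomal protein genes and 18 of 22 genes of ATP synthase and NADH dehydrogenase I. Of these list shifts all but the general stress one were lost with an estimated correlation (adjusted p = 0.453, 0.091, 0.230 and 0.230). The hchA gene rose by 4.27 (SE 0.18, adjusted p = 1.18e-07), from 6.01 ± 0.21 to 10.28 ± 0.24 (SD, n = 3). The homoserine kinase gene thrB fell by 5.58 (SE 0.41, adjusted p = 4.45e-06), from 11.60 ± 0.26 to 6.02 ± 0.71 (SD, n = 3). In all 312 genes were higher and 520 lower, of which 125 and 333 changed at least 2-fold. After quantile normalization the split was 420 higher to 466 lower, and the share of higher genes went from 37.5% to 47.4%. The number of higher genes was 180 without stationary wild type replicate 1 and 183 without stationary wild type replicate 2. The rpoS transcript itself differed by −0.10 (SE 0.19, adjusted p = 0.756), and by 0.49 after quantile normalization (adjusted p = 0.0419).

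Of the 93 general stress genes 51 rose in the stationary wild type, 4 fell and 38 did not pass, with 58 higher and 4 lower adjusted over the list alone (median 0.710, adjusted p = 1.95e-17, and adjusted p = 0.035 with an estimated correlation). After hchA came yodD at 3.83, dps at 3.31 and the glutarate hydroxylase gene glaH at 2.85. Of the 4 that fell, hyaA fell by 1.94 and hyaB by 1.36, while mscS, for a mechanosensitive channel, fell by 1.68 and yaiA by 0.55; these 4 were named after their values were seen. Trehalose and osmotic stress genes rose in 6 of 20 cases and fell in 1, with the same counts adjusted over the list alone (median 0.311, adjusted p = 0.00327, but adjusted p = 0.174 with an estimated correlation). The osmY gene rose by 2.47 and otsB by 1.82, and the compatible solute transporter gene proP fell by 1.77. Heat shock genes rose in 7 of 18 cases and 0 fell, with 10 higher and 1 lower adjusted over the list alone (median 0.435, adjusted p = 0.00131, but adjusted p = 0.304 with an estimated correlation); clpB rose by 3.04 and dnaK by 2.05. Oxidative stress defence had 4 of 16 higher, with 5 higher and 1 lower adjusted over the list alone (median 0.168, adjusted p = 0.0267, but adjusted p = 0.214 with an estimated correlation). Besides dps these were sodA and sufA, at 1.54 each, and sodC at 0.66.

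Carbon use shifted as well. Of 17 tricarboxylic acid cycle genes 12 rose and 2 fell, with 13 higher and 3 lower adjusted over the list alone (median 1.586, adjusted p = 8.84e-05, but adjusted p = 0.312 with an estimated correlation); sdhD rose by 2.37, sucC, for succinyl-CoA synthetase, by 2.34 and sucB by 2.23. Of 12 genes of glyoxylate bypass and acetate use 7 rose and 2 fell, under both adjustments, by all genes and adjusted over the list alone (median 0.949, adjusted p = 0.0099, but adjusted p = 0.453 with an estimated correlation). The acetyl-CoA synthetase gene acs rose by 3.39, aceA by 3.38 and aceB by 2.67. Of 17 genes of tryptophanase and amine catabolism 9 rose and 0 fell, with 10 higher adjusted over the list alone (median 0.575, adjusted p = 0.000982, but adjusted p = 0.214 with an estimated correlation). The putrescine use gene puuA rose by 1.41 and gabD by 1.18. Of 18 genes of glycolysis 9 fell and 0 rose, with 12 lower adjusted over the list alone (median −0.799, adjusted p = 6.52e-05, but adjusted p = 0.387 with an estimated correlation). The phosphoglycerate mutase gene gpmM fell by 3.09 and the pyruvate kinase gene pykA by 1.93. Of 24 genes of fermentation 12 fell and 0 rose, with 13 lower adjusted over the list alone (median −0.877, adjusted p = 2.58e-06, but adjusted p = 0.230 with an estimated correlation); dcuB fell by 2.28 and pflB by 1.97. Outside the lists, cspD, an inhibitor of DNA replication, rose by 3.05 and ychH by 2.55, the latter read by a probe set that can cross-hybridise. The pyruvate dehydrogenase gene aceE fell by 3.97.

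Biosynthetic genes were lower in the stationary wild type. Of 61 amino acid biosynthesis genes 45 fell and 0 rose, with 48 lower adjusted over the list alone (median −1.675, adjusted p = 2.1e-27, but adjusted p = 0.091 with an estimated correlation). After thrB, the largest falls were those of the histidine genes hisH, by 4.31, and hisD, by 4.25, and of thrA, by 4.16. The acetolactate synthase gene ilvG, outside the list, fell by 4.13. Outside the lists 3 oligopeptide permease genes fell, with log2 fold changes of −5.06 for oppA, −4.80 for oppD and −4.31 for oppB. The Spot 42 small RNA gene spf fell by 4.53. Of 54 ribosomal protein genes 41 fell and 0 rose, with 43 lower adjusted over the list alone (median −1.300, adjusted p = 2.88e-21, but adjusted p = 0.230 with an estimated correlation); rpmC fell by 3.29. Of 22 genes of ATP synthase and NADH dehydrogenase I 18 fell and 0 rose, with 20 lower adjusted over the list alone (median −1.136, adjusted p = 2.3e-12, but adjusted p = 0.230 with an estimated correlation); atpA fell by 2.84. Of 9 type 1 fimbrial genes 5 fell and 0 rose, with 7 lower adjusted over the list alone (median −0.607, adjusted p = 0.000349, but adjusted p = 0.230 with an estimated correlation); fimA fell by 3.09.

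Of the other lists in the stationary wild type, 3 passed with small shifts that did not hold with an estimated correlation. Flagella had 4 of 54 genes higher and 0 lower, and 0 adjusted over the list alone (median 0.251, adjusted p = 0.00444, adjusted p = 0.466 with an estimated correlation); on these same wild type arrays 6 of the genes from flhD to tap were at background. The call of flgM, an anti-sigma factor gene that differed by 0.67, was lost without stationary wild type replicate 1 (adjusted p = 0.0705) or replicate 2 (adjusted p = 0.0702). Iron acquisition had 3 of 33 higher, 2 adjusted over the list alone (median 0.142, adjusted p = 0.0296, adjusted p = 0.453 with an estimated correlation), and cryptic prophages 3 of 24, also 3 adjusted over the list alone (median 0.308, adjusted p = 0.0126, adjusted p = 0.504 with an estimated correlation). After quantile normalization these became 0.193 and 0.0609, and without dim genes 0.0594 and 0.19. Acid resistance had 4 of 15 higher, with 6 higher and 1 lower adjusted over the list alone, and did not pass as a list (median 0.225, adjusted p = 0.0687). In that list gadA rose by 2.5 and gadC by 1.62. After quantile normalization the list passed (adjusted p = 0.00368). Nucleoid proteins and ribosome hibernation had 6 higher and 1 lower of 16, with 7 and 1 adjusted over the list alone (adjusted p = 0.0687, and 0.00137 after quantile normalization); raiA, a ribosome hibernation gene, rose by 2.35. Phosphate starvation had 0 of 17 called, also 0 adjusted over the list alone (adjusted p = 0.653), and its smallest gene p was that of pstC at −0.55 (adjusted p = 0.0509). Nitrogen limitation had 5 higher and 9 lower of 26, with 7 and 11 adjusted over the list alone (adjusted p = 0.302); the glutamine synthetase gene glnA fell by 2.57.

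Genes lower in the stationary mutant were set against the wild type phase response. Of the 256 lower in the mutant, 92 were higher in the stationary wild type, where independent lists would share 19.1, and 78 were lower there, against 31.8. Of the 40 higher in the mutant, 7 were higher and 4 lower in the stationary wild type, against 2.98 and 4.97. These comparisons share the stationary wild type arrays. Fold changes had r = 0.019 across genes, where 50 simulations of unchanged groups sharing these arrays gave −0.497, and a covariance of 0.0089 against −0.0276, a difference of 0.0365. The simulated groups held no real changes and gave a mean overlap of 0. They therefore do not show how much of the 92 comes from the shared arrays. With 3 shared arrays the controls could not be split into separate sets of at least 2, so part of the 92 can come from the shared controls, whose noise moves the comparisons in opposite directions.

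In the mutant, the comparison of stationary with exponential phase gave the phase response without RpoS. In stationary phase 50 of 54 flagellar, 53 of 54 ribosomal protein and 15 of 18 glycolytic genes were lower, as were all 22 of ATP synthase and NADH dehydrogenase I, while 9 of 15 acid resistance and 33 of 93 general stress genes were higher. Of these list shifts only the flagellar one held with an estimated correlation (the others in this order had adjusted p = 0.263, 0.266, 0.266, 0.392 and 0.266). The ribosomal gene rpmC fell by 6.63 (SE 0.50, adjusted p = 1.46e-06) and fliM fell by 6.49 (SE 0.21, adjusted p = 2.14e-09). The carbon starvation gene cstA rose by 2.96 (SE 0.19, adjusted p = 5.52e-07), from 9.78 ± 0.17 to 12.74 ± 0.38 (SD, n = 3). In all 832 genes were higher and 884 lower, of which 146 and 608 changed at least 2-fold. After quantile normalization the split was 1152 higher to 808 lower, and the share of higher genes went from 48.5% to 58.8%. The number of higher genes was 419 without stationary mutant replicate 2, 508 without stationary mutant replicate 3, 514 without exponential mutant replicate 2 and 512 without exponential mutant replicate 3. Calls were shared with the wild type for 165 higher and 410 lower genes, where independent lists would share 62.0 and 110.

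Of 54 flagellar genes 50 fell in the stationary mutant and 0 rose, with 52 lower adjusted over the list alone (median −3.044, adjusted p = 1.45e-37, and adjusted p = 0.0318 with an estimated correlation). The motB gene fell by 5.68 and flgF by 5.21; the wild type, where 6 genes from flhD to tap were at background, does not enter this comparison. Of 54 ribosomal protein genes 53 fell, also 53 adjusted over the list alone (median −2.935, adjusted p = 2.18e-34, but adjusted p = 0.263 with an estimated correlation); rpsB fell by 5.6 and rpsP by 5.40. All 22 genes of ATP synthase and NADH dehydrogenase I fell, also 22 adjusted over the list alone (median −2.183, adjusted p = 4.64e-14, but adjusted p = 0.266 with an estimated correlation). Amino acid biosynthesis fell in 36 of 61 cases, also 36 adjusted over the list alone (median −0.944, adjusted p = 5.3e-11, but adjusted p = 0.266 with an estimated correlation), with thrB at −5.04. In glycolysis 15 of 18 fell and 1 rose, the same adjusted over the list alone (median −1.703, adjusted p = 9.71e-09, but adjusted p = 0.266 with an estimated correlation); ptsH fell by 4.61. Fimbriae fell in 7 of 9 cases, also 7 adjusted over the list alone (median −1.223, adjusted p = 0.000584, but adjusted p = 0.266 with an estimated correlation).

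General stress genes still rose in 33 of 93 cases in the mutant and fell in 2, with 31 and 2 adjusted over the list alone (median 0.470, adjusted p = 3.03e-05, but adjusted p = 0.266 with an estimated correlation). The glgS gene rose by 1.68 and yodD by 1.59. Acid resistance genes rose in 9 of 15 cases, also 9 adjusted over the list alone (median 0.658, adjusted p = 0.00289, but adjusted p = 0.392 with an estimated correlation), yhiD by 1.03 and dctR by 1.09. Tryptophanase and amine catabolism rose in 7 of 17 cases, also 7 adjusted over the list alone (median 0.527, adjusted p = 0.00289, but adjusted p = 0.266 with an estimated correlation), with tnaC at 1.29 and tnaA at 1.18. Curli had 5 of 9 higher, 6 adjusted over the list alone (median 0.686, adjusted p = 0.0416, but adjusted p = 0.392 with an estimated correlation, adjusted p = 0.136 after quantile normalization, 0.101 without dim genes and 0.0599 with all probe sets). The curli subunit gene csgA rose by 1.22. Transport of other carbon sources had 9 higher and 4 lower of 31, the same adjusted over the list alone (median 0.325, adjusted p = 0.0488, but adjusted p = 0.392 with an estimated correlation and 0.104 with all probe sets), with the dicarboxylate transporter gene dctA up by 2.19. Outside these lists cspD rose by 3.05, raiA by 2.59, ychH by 2.31 and the allantoinase gene allB by 2.19. In oxidative stress defence, 4 higher and 3 lower of 16, 4 and 4 adjusted over the list alone, the median was 0.084, the mean −0.121 and the test pointed up (adjusted p = 0.844).

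The interaction tested whether the mutant minus wild type difference changed between the phases, as the stationary minus the exponential difference. It was lower in stationary phase for 49 of 54 flagellar, 42 of 54 ribosomal protein, 9 of 17 tricarboxylic acid cycle and 19 of 93 general stress genes, and higher for 7 of 61 amino acid biosynthesis genes. Of these list shifts only the flagellar one held with an estimated correlation (the others had adjusted p = 0.223, 0.278, 0.223 and 0.373). For hchA the interaction was −4.05 (SE 0.25, adjusted p = 9.57e-07) and for lysC 3.68 (SE 0.57, adjusted p = 0.0017). In all 63 genes had a higher and 262 a lower interaction, of which 49 and 241 were at least 2-fold. After quantile normalization these were 136 and 237, so the share of higher genes went from 19.4% to 36.5%. The number of higher interactions was 40 without stationary wild type replicate 1 and 39 without stationary wild type replicate 2.

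Flagella held 49 of 54 lower interactions and 0 higher, with 53 lower adjusted over the list alone (median −3.298, adjusted p = 4.41e-77, and adjusted p = 0.00268 with an estimated correlation). Values were −6.68 for fliM, −5.72 for flgF and −5.63 for fliF, while for motB the wild type was at background in both phases, as in 6 of the genes from flhD to tap. Of 54 ribosomal protein genes 42 had a lower interaction, 53 adjusted over the list alone (median −1.653, adjusted p = 3.4e-32, but adjusted p = 0.223 with an estimated correlation). For rpsB it was −4.00 (SE 0.48). Of 17 tricarboxylic acid cycle genes 9 had a lower one, with 13 lower and 1 higher adjusted over the list alone (median −2.057, adjusted p = 1.36e-06, but adjusted p = 0.278 with an estimated correlation). For sdhB it was −3.31 and for sucB −3.07. Heat shock had 6 of 18 lower, 12 adjusted over the list alone (median −1.065, adjusted p = 7.72e-06, but adjusted p = 0.223 with an estimated correlation), with dnaK at −2.45. General stress genes had 19 lower and 2 higher of 93, with 24 and 2 adjusted over the list alone (median −0.267, adjusted p = 2.37e-05, but adjusted p = 0.223 with an estimated correlation). Among these dps was at −3.47 and hyaA at 2.59. Fermentation had 5 of 24 higher, also 5 adjusted over the list alone (median 0.529, adjusted p = 1.46e-05, but adjusted p = 0.278 with an estimated correlation), with dcuB at 2.52. Amino acid biosynthesis had 7 higher and 2 lower of 61, with 9 and 3 adjusted over the list alone (median 0.604, adjusted p = 0.000107, but adjusted p = 0.373 with an estimated correlation). After lysC came lysA at 2.54 and dapB at 2.05. Outside the lists, yjiG was at 3.33, oppA at 2.93 and cydX, a small subunit of cytochrome bd read through an intergenic probe set, at 2.74.

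**Figure D4:**
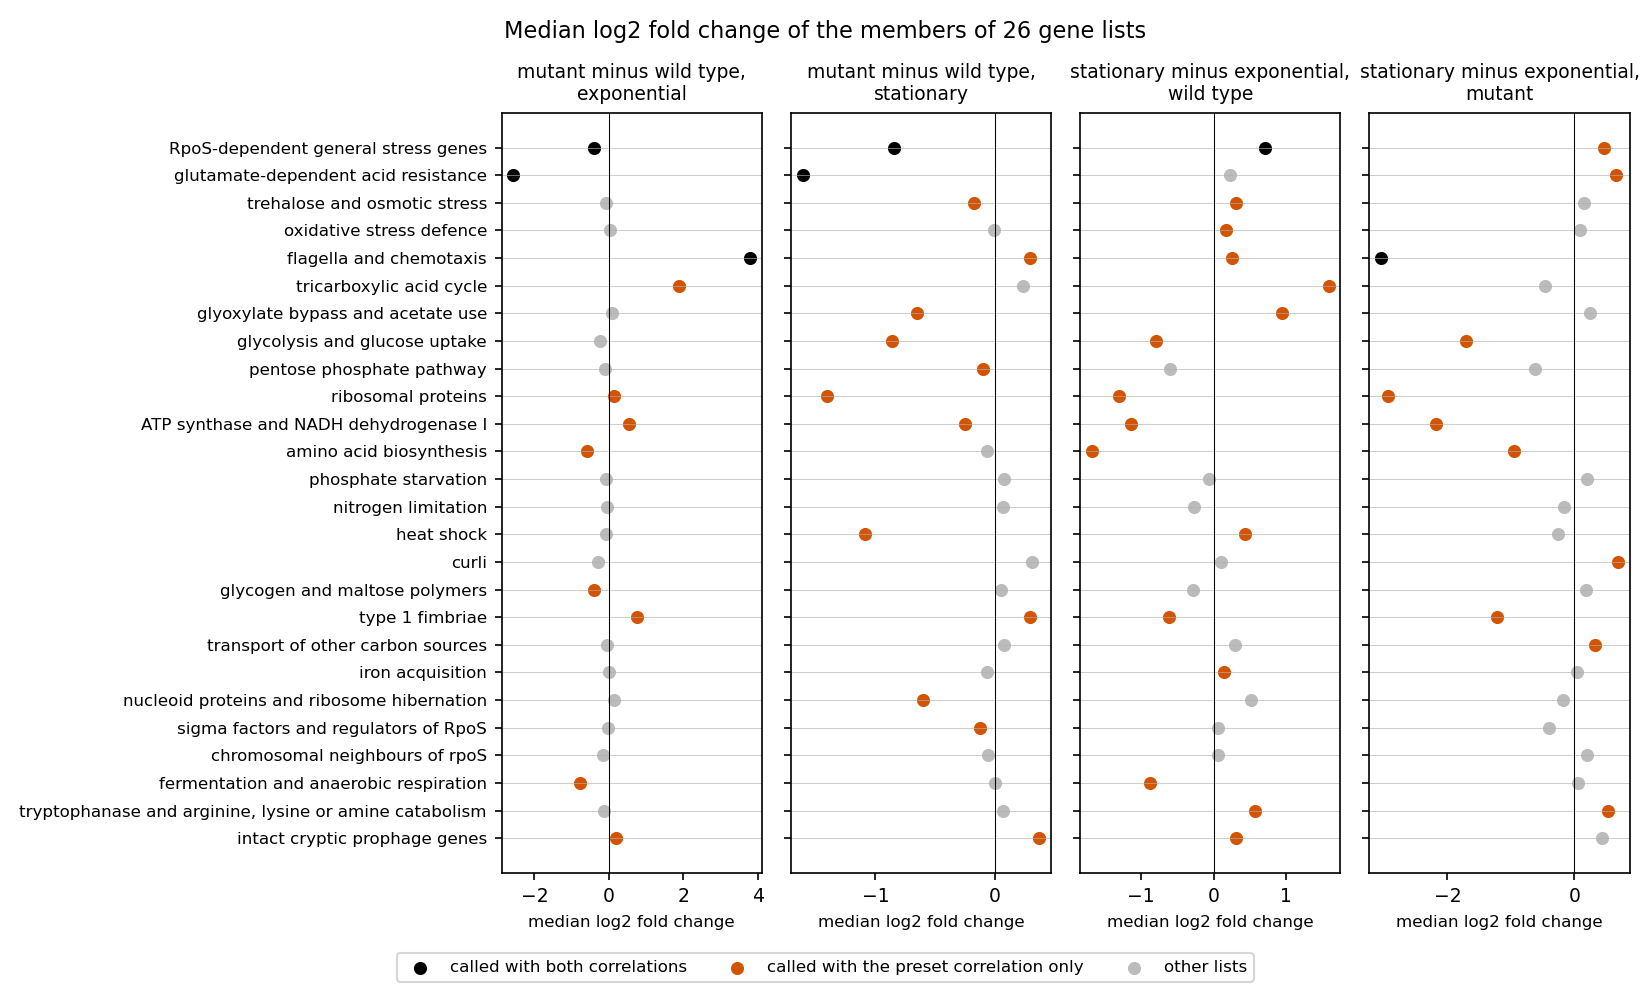
Median log2 fold change (x axis) of 26 gene lists (y axis) in 4 comparisons, 1 panel each. Black points passed with both the preset and the estimated correlation, orange points with the preset correlation alone and grey points with neither. In the exponential mutant flagella lay at 3.797 and acid resistance at −2.566.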

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

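The tests on flagellar genes, on scaling and on growth stage were chosen after the result was seen; those on oxygen supply and on regrouped arrays were set beforehand.

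Flagellar genes were higher in the exponential mutant, and the 8 neighbours from flhD to tap were higher in both phases. Of these 8, 6 were at background on all 6 wild type arrays, and of the other 46 flagellar genes 0 were, so a wild type stock lacking the segment is a possible explanation. An intact but silent segment cannot be told apart from this: the median stationary difference of the 8 exceeded that of the other 46 by 5.75, but it rests on wild type values at background and comes out alike in both cases. For the other 46, with an exponential median of 3.48, absence of the FlhDC regulator could not be separated from loss of rpoS, because no array held rpoS with flhD expressed or lacked both. In ASM584v2 the insertion sequence genes insB5 and insA5 lie between flhD and uspC.

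In the exponential mutant 14 of 17 tricarboxylic acid cycle genes were higher and 10 of 24 fermentation genes lower, list shifts that were lost with an estimated correlation (adjusted p = 0.136 and 0.155). Genes lower without oxygen exceeded those higher without oxygen by 0.80 in median log2 fold change, so better aeration of the mutant cultures may contribute. The 30 genes higher without oxygen had a median of −0.734 and passed as a list, while the 17 lower without oxygen had 0.061, with 4 higher and 0 lower, and missed the bar set beforehand. Array medians of the 17 were 9.1, 8.6 and 8.48 in exponential wild type replicates 1 to 3, so replicate 1 stood apart. In the exponential mutant replicates they were 8.72, 8.63 and 8.64. Quantile normalization left the tricarboxylic acid cycle median at 1.53, so the array differences that this step removes did not account for the shift. Other forms of scaling were not ruled out. Oxygen supply stays open.

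In the stationary mutant 41 of 54 ribosomal protein genes were lower, a list shift that was lost with an estimated correlation (adjusted p = 0.0932). After quantile normalization their median was still −1.18, so the array differences that this step removes did not account for the shift. Other forms of scaling were not ruled out. A later growth stage of the mutant cultures stays open. The 102 bright non-ribosomal genes that fell in the stationary wild type had a median mutant minus wild type difference of −0.33, but they were chosen on the same stationary wild type arrays, so this value does not decide.

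Regrouping the arrays left 1 of 10 splits with as many calls as the real one in each of the 4 pairwise comparisons. The real counts were 323, 296, 832 and 1716 and the highest others 11, 0, 0 and 0, and 10 splits are too few for a share under 0.05. For the interaction 3 of 100 splits had as many calls, with 325 in the real one and 744 in the highest other. Groups held 3 arrays, so outliers were not tested.

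The mutant minus wild type difference changed between phases for 63 genes upward and 262 downward. Without the flagellar genes, a setting chosen after seeing the data, these counts were 57 and 202. The flagellar interactions cannot be assigned to loss of rpoS, given the wild type background of flhD and flhC described above. Interactions upward were lysC 3.68, yjiG 3.33, oppA 2.93, cydX 2.74, spf 2.73, hyaA 2.59, ompF 1.99 and hisD 1.36. Those of flagellar genes were fliM −6.68, flgF −5.72, fliF −5.63, fliZ −5.31 and tar −4.82. With wild type values at background in both phases, cheA had −3.40, cheW −2.60, flhC −1.79, motA −5.17 and motB −5.68; tap, at background on 5 of the 6 wild type arrays, had −3.61. Those of stress and metabolic genes were hchA −4.05, dps −3.47, aceA −3.19, gadA −2.52, aceB −2.48, yodD −2.25, clpB −2.24, glaH −1.97 and gadC −1.36. Those of ribosomal genes were rpsB −4.00, rpmC −3.34 and rpsP −3.17.

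Of 15 lists called for the interaction only flagella kept the call with an estimated correlation. Median interactions were −3.298 for flagella (adjusted p = 0.00268 with an estimated correlation), −2.057 for the tricarboxylic acid cycle, −1.653 for ribosomal proteins, −1.067 for glycolysis, −1.065 for heat shock and −0.811 for ATP synthase and NADH dehydrogenase I. With an estimated correlation the last 5 had adjusted p = 0.278, 0.223, 0.298, 0.223 and 0.373. Smaller ones were −0.586 for nucleoid proteins, −0.267 for general stress, −0.253 for sigma factors and −0.225 for trehalose, with adjusted p = 0.298, 0.223, 0.298 and 0.223 with an estimated correlation. Sigma factors were also lost after quantile normalization (adjusted p = 0.103) and trehalose without dim genes (adjusted p = 0.0573). Upward medians were 0.670 for curli, 0.604 for amino acid biosynthesis, 0.529 for fermentation, 0.380 for glycogen and 0.238 for phosphate starvation, with adjusted p = 0.298, 0.373, 0.278, 0.278 and 0.373 with an estimated correlation. Curli had 0 of 9 genes called and was lost without dim genes (adjusted p = 0.328), and phosphate starvation had 0 of 17 called.

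Of 2828 intergenic probe sets not assigned to a gene, 24 were higher and 35 lower in the exponential mutant, and 41 higher and 70 lower in the stationary mutant.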

How the results depend on the processing

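All settings were chosen beforehand except leaving out the flagellar genes, a test chosen after the result was seen, which left 116 genes higher in the exponential mutant where all genes gave 175.

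Array weights gave 568 higher and 440 lower genes in the exponential and 289 and 498 in the stationary mutant, 951 higher in the wild type and 1434 higher in the mutant phase comparison, and 412 higher and 702 lower interactions, 525 of them at least 2-fold. The weights ran from 0.243 to 4.07 and their fit gave a convergence warning, so little rests on them.

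A threshold of 0.01 left 114 higher and 92 lower genes in the exponential mutant and 17 higher in the stationary mutant. It left 134 higher and 304 lower in the wild type phase comparison, 266 higher in the mutant one, and 28 higher and 148 lower interactions, 174 at least 2-fold. Fitting 6 arrays alone gave 107 higher and 74 lower in the exponential and 140 higher and 367 lower in the stationary mutant. The main fit, which pooled the variance of all groups, gave 175 and 148 in exponential and 40 and 256 in stationary phase. Median SDs were 0.244 in each exponential group and 0.160 and 0.151 in the stationary wild type and mutant. How the number of calls compares between the phases therefore depends on this pooling. Quantile normalization gave 156 higher in the stationary mutant, 136 higher interactions and 22 genes higher in both phases. It moved the sign of rpoS in the wild type phase comparison to 0.49, and in the mutant one that of sodB to 0.33 and of lpd to 0.24. Testing all probe sets gave 87 higher in the stationary mutant and 1503 higher in the mutant phase comparison. Median centring, the dim filter, the variance trend and the replicate block moved no count more than 1.5 times.

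Leaving out 1 replicate gave 132 to 285 higher genes in the exponential mutant, the latter without wild type replicate 1, and 21 to 37 in the stationary mutant. It gave 180 to 398 in the wild type and 419 to 918 in the mutant phase comparison, and 39 to 94 higher interactions. With the replicate number as a block 182 genes were higher and 152 lower in the exponential mutant. After group means were removed, correlations between arrays of the same number ran from −0.19 to 0.36, and in no pair of groups did all 3 arrays correlate best with their own number.

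Among list results, an estimated correlation ended 59 calls and left 71 results unchanged, mostly lists not called either way. Called lists went from 11 to 3 in the exponential and from 14 to 2 in the stationary mutant. They went from 16 to 1 in the wild type phase comparison, from 11 to 1 in the mutant one and from 15 to 1 in the interaction. Quantile normalization ended 9 calls and added 6, the dim filter ended 7 and added 5, and testing all probe sets ended 2 and added 7. Median centring and the replicate block each ended 0 and added 1. Among named genes, leaving out 1 replicate ended 354 calls and left 2827 results unchanged. These counts are summed over all such fits, and the unchanged results include genes not called either way.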

Other observations

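In both growth phases and both genotypes, 11 genes were at background on all 12 arrays: yahJ, lacY, lacZ, rutD, yceO, ychS, hokD, valW, dsrA, leuU and yjbG. The adjacent genes lacZ and lacY read 1.90 ± 0.06 and 1.95 ± 0.08 (SD, n = 12). Their neighbours lacI and lacA were at background on 0 arrays. These genes were picked out after their values were seen.

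Across all 4185 genes, 24 were at background on all 6 wild type arrays. Only flhD, flhC, motA, motB, cheA and cheW were so while their mutant mean lay more than 2-fold above the mean background of the mutant arrays. Of the 24, 11 were at background on all 12 arrays. Apart from flhD, flhC, motA, motB, cheA and cheW, the others rose above background on some mutant arrays, but their mean did not by that margin.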
